A study of Mus musculus with 12 samples.

How the data were processed

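The data are 12 single-colour Agilent whole-genome mouse arrays, each hybridised with Cy3-labelled cRNA from C3H/10T1/2 cells, a mouse embryonic fibroblast line. Per the labels, 2 stable lines carried either a short hairpin against Six4 (shSix4) or a control hairpin (shLuc). Each line was infected with a retrovirus for MyoD or with the empty pBABE vector, and 24 h later was moved for 24 h into medium with 2% horse serum. This gives 4 groups of 3 arrays, assigned from the sample titles, which the source and characteristics fields match. The description field of the samples names another muscle cell line and other stages, contradicts all other fields and was not used. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

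Each deposited scanner file holds the spots of 1 array as Cy3 intensity on a linear scale, extracted by the authors with Agilent Feature Extraction. Its version is 11.5.1.1 per the file headers and 10.5.1.1 per the submitters' processing notes. The processed signal used here is background-corrected and detrended within its array, per the file headers, and not normalized between arrays. The authors also deposited a table of normalized values on a log2 scale. Set against the scanner values, each of its columns followed log2 of its own array's processed signal (r 0.9993 to 0.9998 across probes, slope 0.959 to 1.05). Its column medians lie between 8.66 and 8.72, so the arrays are levelled and genes are not centred. Its name refers to quantile normalization, and no label or comment line used here states the method. Its values are levels, with no direction to settle. The copy used here holds 3891 different probes, of which 3867 are among the non-control probes, and it served only as an alternative.

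Each array carries 45018 spots, 43379 of them non-control. Control spots and spots with an outlier mark were left out and spots of the same probe were averaged, which left 41174 probes. No spot was saturated. From log2 of the processed signal each array's 75th percentile was subtracted. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which 24000 probes were. Probes were named through the RefSeq accession in the scanner files and a table of RefSeq genes (assembly GRCm38.p6), used for names only. It matched 24820 of 25268 probes with an mRNA accession and 24 of the other 15906, which left 16330 probes unnamed. No coordinates are given, because the array design used an older build. For each gene the named probe with the highest mean over all arrays was taken, which gave 12300 genes. Among the 772 genes called for MyoD in shLuc cells, 215 had 2 or more kept probes, and in 7 of these another probe had the opposite sign, past the threshold in 0. In shSix4 cells this held for 1 of 93 such genes. Outlier marks left 173 values missing in 156 genes. The number of arrays limits the precision.

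Genes were tested with limma 3.58.1 in R 4.3.3 (labels read with jsonlite 2.0.0), with a mean per group over all 12 arrays, 8 residual degrees of freedom and 2.85 prior degrees of freedom. There were 5 comparisons: MyoD against empty vector in each line, shSix4 against shLuc with each vector, and the difference of the MyoD response between the lines (the interaction). P-values were adjusted by Benjamini-Hochberg over the 12300 genes of a comparison, with a threshold of 0.05, and all p-values printed for genes are adjusted unless stated otherwise. Errors of log2 fold changes are limma standard errors (SE). Where a gene was well above background on no array of a group, its change is given as a bound. The bound is the brighter group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. It holds for the signal and scaling used here, and some genes read below their bound under the alternatives.

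The lists, 22 in number, were sarcomere and contractile apparatus, myogenic transcription factors and cofactors, Six-Eya-Dach family, inhibitors of myogenic bHLH factors, excitation-contraction coupling and neuromuscular junction, muscle energy metabolism, myoblast fusion and adhesion, cell cycle, CDK inhibitors and retinoblastoma family, fibroblast extracellular matrix, adipocyte, osteoblast, chondrocyte and smooth muscle markers, leukocyte and endothelial markers, interferon response, H3K27 methylation writers and erasers, Notch pathway, insulin-like growth factor axis, unfolded protein and amino acid stress response, cholesterol biosynthesis, and p53 target genes. Each was tested in each comparison with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists and comparisons. MyoD-induced and MyoD-repressed sets were chosen on the MyoD response averaged over both lines (adjusted p under 0.05 and at least 2-fold), a choice that does not bias the sign of the interaction, and their set p-values are adjusted over both sets, the interaction and the comparisons between the lines, an adjustment chosen after the values were seen. Named genes are Six4 and Myod1, per comparison up to 10 called genes each with the highest and lowest log2 fold changes whose groups of 3 arrays do not overlap (clone and predicted names left out), and per list up to 4 called members with the largest changes or, with none called, the member with the largest change. One gene that the rule takes is not reported here. Names outside this rule are marked as chosen after their values were seen. Groups, lists, tests, this rule and most alternatives were fixed before the data were examined.

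The arrays lie on 3 slides of 4, each holding 1 array of every group. The replicate number in the titles is the slide, and slide 1 was scanned on another day than slides 2 and 3. Deviations from the group means correlated across genes between arrays of the same slide in all 18 pairs (r 0.278 to 0.819, median 0.646). Arrays of different slides and groups lay between -0.733 and 0.498 (median -0.545), where subtracting group means itself favours negative values. These ranges overlap, with the highest values between slides 2 and 3. The numbers thus pair the samples, most clearly on slide 1. The second principal component (26.2% of the variance) was 86.8% explained by slide, the first (51.0%) 88.2% by vector and the third (7.67%) 76.5% by line. The fit planned without a block remains the reported result, and blocked values (6 residual degrees of freedom) stand beside results they change.

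The fit was tested on simulated data of 12144 genes with 200 genes changed in shSix4 cells with MyoD. For shSix4 against shLuc with MyoD it recovered 0% of genes changed 1.5-fold, 2.5% of those changed 2-fold and 69.5% of those changed 4-fold, and with the slide as a block 0%, 82.0% and 94.5%. For the interaction the shares were 0%, 0% and 40.0%, and with the block 0%, 20.0% and 90.5%. For shSix4 against shLuc with the empty vector, where no change was simulated, 0 genes were called. Among unchanged genes 0 and 2 were called for the lines with MyoD at 2-fold and 4-fold and 0 and 0 in the interaction, and with the block 6 and 15, and 3 and 14. Lists of 50 genes shifted by -0.5 (log2) in the interaction passed camera with an estimated correlation in 10 of 10 runs, and unchanged lists in 0 of 10, with and without the block. At the preset correlation unchanged lists passed in 1 of 10 runs, or 0 of 10 with the block. The simulated noise was independent between genes and between arrays, and the lists were drawn at random. Real sets vary together, with an estimated correlation of 0.163 for MyoD-induced and 0.226 for MyoD-repressed genes without the block. These list rates therefore may not hold for the lists tested. Real differences between the lines also shared a part by slide. They correlated between the vectors at r 0.338 within slide 1, against 0.0955 to 0.170 between slide 1 and another slide. Such a part was not simulated, so the gene rates for the lines, above all with the block, may not hold either.

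The alternatives tried were normexp background correction with an offset of 50 (on the median spot signal, since a mean signal was not used here), quantile normalization, the authors' table, no filter on dim probes, probes well above background on all 12 arrays, every probe, only the groups compared, the replicate number or the slide as a block (identical here), a trended and robust moderation, array weights, and each array left out in turn. A random slide effect was not run because every slide holds all groups. Added after seeing the data were the arrays without slide 1, plain background subtraction with an offset of 50, and outlier-marked spots kept for Myod1.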

Results

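Gene expression was profiled on 12 single-colour arrays from C3H/10T1/2 fibroblasts, which turn towards skeletal muscle when made to express MyoD, the basic helix-loop-helix factor that starts the muscle programme. Stable lines with a hairpin against Six4, a homeobox transcription factor, or with the control hairpin shLuc received MyoD or an empty vector and were differentiated for 24 h, giving 4 groups of 3 arrays. The design asks how the loss of Six4 changes conversion to muscle. Between 22318 and 27448 of 41174 probes were well above background per array. Their number was 25126 ± 1870 (SD, n = 3) in shLuc cells with empty vector, 24463 ± 922 in shLuc cells with MyoD, 23655 ± 1193 in shSix4 cells with empty vector and 25394 ± 2506 in shSix4 cells with MyoD. Across 12144 genes, arrays of the same group correlated at r 0.955 to 0.993 and arrays of different groups at 0.903 to 0.991.

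Six4 was lower in shSix4 than in shLuc cells on each of the 3 slides with either vector, but not past the threshold. Its level relative to each array's 75th percentile (log2) was -2.62, -2.90 and -1.64 in shLuc cells with empty vector and -4.10, -3.00 and -2.82 in shSix4 cells with empty vector. With MyoD it was -1.45, -1.69 and -0.85 in shLuc cells and -3.03, -2.93 and -1.54 in shSix4 cells. The log2 difference between the lines was -1.17 ± 0.49 (SE) with MyoD (adjusted p = 0.558) and -0.92 ± 0.49 with empty vector (adjusted p = 0.999). With the slide as a block the difference with MyoD passed the threshold (adjusted p = 0.0424, range over the alternatives 0.0424 to 0.961) and that with empty vector did not (0.168). Within slides 1, 2 and 3 it was -1.59, -1.24 and -0.69 with MyoD and -1.48, -0.096 and -1.19 with empty vector. Six4 showed +1.05 ± 0.49 with MyoD in shLuc cells (adjusted p = 0.272, and 0.0200 with the block) and +0.80 ± 0.49 in shSix4 cells (adjusted p = 0.742).

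Myod1, measured by 1 probe, was at 0.071, -0.23 and 1.23 in shLuc cells with MyoD and at -2.17, -0.86 and -0.23 in shSix4 cells with MyoD. In the empty-vector groups its spot carried an outlier mark on slide 3, and the other arrays read -4.77 and -2.57 in shLuc and -4.37 and -2.01 in shSix4 cells. Myod1 rose by 4.03 ± 0.90 in shLuc cells (adjusted p = 0.0315). In shSix4 cells it read +2.10 ± 0.90, which did not pass (adjusted p = 0.482), and the test of this difference between the lines gave -1.92 (adjusted p = 1.00). With outlier-marked spots kept, an alternative chosen after seeing the data, the changes were 3.55 (adjusted p = 0.0338, range over the alternatives 0.00257 to 0.930) and 1.51, which did not pass. Among cells with MyoD, Myod1 was -1.45 ± 0.81 in shSix4 against shLuc cells (adjusted p = 0.837), and lower on each slide. Whether the probe reads the viral transcript is not given in the sources used here. Leaving out 1 array ended the call in shLuc cells for shLuc replicate 1 with empty vector (2.93), shLuc replicates 1, 2 and 3 with MyoD (4.17, 4.32 and 3.59) and shSix4 replicate 2 with MyoD (adjusted p = 0.0518). The plot of levels per array shows both genes with 4 muscle genes.

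**Figure D1:**
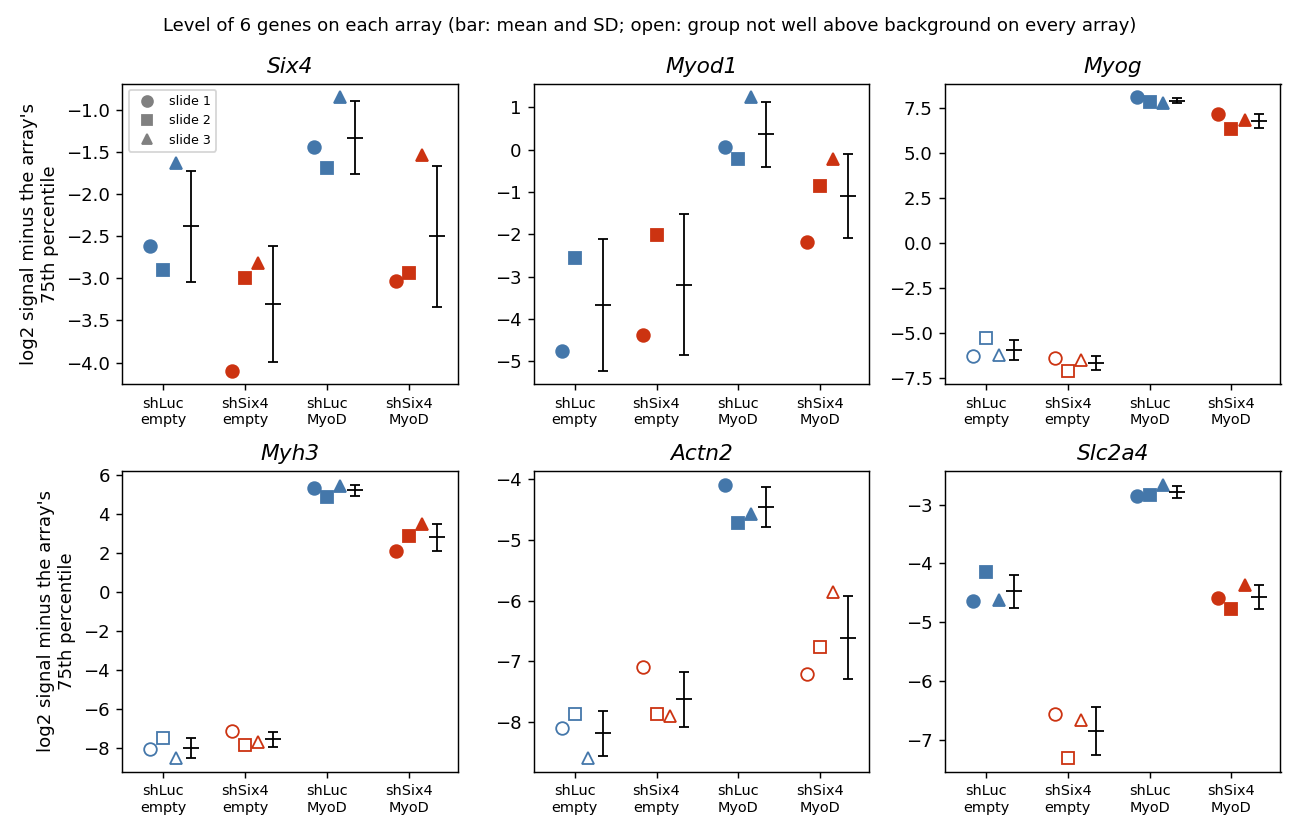
Log2 levels of Six4, Myod1, Myog, Myh3, Actn2 and Slc2a4 relative to each array's 75th percentile, with a symbol per array (circle, square and triangle for slides 1, 2 and 3), blue for shLuc and red for shSix4, bars for the mean ± SD and open symbols for groups not well above background on every array. Myh3 was on average -2.40 lower in shSix4 than in shLuc cells with MyoD, and Myod1 lacks both slide 3 values with empty vector.

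In shLuc cells, MyoD switched on the muscle programme. Myog, the transcription factor that drives terminal muscle differentiation, rose by 13.85 ± 0.31 (log2, SE, n = 3 against 3), and was above background on 1 of 3 empty-vector arrays. The embryonic myosin heavy chain Myh3 was at least 2311-fold higher, the light chain Myl1 at least 1965-fold and the fetal acetylcholine receptor subunit Chrng at least 2691-fold. Over the alternatives the change of Chrng was as low as 7.74 (log2), which is below its bound. The myosin chaperone Unc45b was at least 682-fold and the perinatal myosin heavy chain Myh8 at least 558-fold higher. Chrna1 rose by 10.73 ± 0.32 and Myh1 by 10.09 ± 0.73, each measured on 1 of 3 empty-vector arrays (6.72 for Chrna1 with normexp, and 1.97 for another probe of Myh1 in the authors' table), Tnnc2 by 10.37 ± 0.35 and Mylpf by 9.55 ± 0.40. The lowest changes were smaller. Kndc1 was at least 1.66-fold, Btc at least 2.82-fold and Stac at least 2.80-fold lower. Acsbg1 fell by 1.98 ± 0.52, Cldn19 by 1.96 ± 0.31, the Wnt ligand Wnt5b by 1.70 ± 0.32, Aff2 by 1.67 ± 0.36, the lipid droplet gene Plin4 by 1.65 ± 0.36 and Tulp2 by 1.59 ± 0.30. Adjusted p of these genes ranged from 1.39e-09 for Myog to 0.0484 for Acsbg1.

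Among muscle lists in shLuc cells, 44 of 52 measured sarcomere genes rose and 8 did not pass (47 rose adjusted over the list alone), with a median log2 change of 6.0, or 5.65 with bounded genes at their bound (adjusted p = 0.00177 with an estimated correlation). Of 30 genes for excitation-contraction coupling and the neuromuscular junction 24 rose (25 adjusted over the list alone, median 4.93, or 4.14 with bounds, adjusted p = 0.00193 with an estimated correlation). Among them were the calcium-binding Hrc by at least 298-fold and the calcium channel subunit Cacng1 by at least 108-fold. Over the alternatives Cacng1 read as low as 3.31 and the metabolism gene Cox8b as low as 3.85 (log2), both below their bounds. Of 22 energy metabolism genes 11 rose (13 adjusted over the list alone, median 1.15, adjusted p = 0.0291 with an estimated correlation). Cox8b was at least 197-fold and myoglobin (Mb) at least 131-fold higher, muscle creatine kinase Ckm was up by 6.74 ± 0.49 (above background on 1 of 3 empty-vector arrays) and Pgam2 by 5.12 ± 0.35. Of 25 myogenic transcription factors and cofactors 10 rose (adjusted over the list alone 13 rose and 1 fell, median 0.60, adjusted p = 0.00361 with an estimated correlation, range over the alternatives 0.00240 to 0.367, with a median of 0.0028 in the authors' table). Rbm24 rose by 9.09 ± 0.42, Sox8 by at least 44.5-fold and Vgll2 by at least 6.73-fold. Of 18 Notch pathway genes 7 rose (8 adjusted over the list alone, median 0.48, adjusted p = 0.0280 with an estimated correlation, 0.101 with the slide as a block, range over the alternatives 0.0110 to 0.413). The ligand Dll1 rose by 5.68 ± 0.30, Jag2 by at least 5.98-fold, Hey1 by 2.84 ± 0.32 and Hes6 by 2.59 ± 0.22. The Notch call ended without shLuc replicate 2 with MyoD (adjusted p = 0.0599), shSix4 replicate 1 with MyoD (0.0765) or shSix4 replicate 1 with empty vector (0.0592), and the median was -0.0072 among probes well above background on all arrays. The metabolism call ended without any 1 of the shLuc empty-vector arrays (0.0507, 0.0547 and 0.0586) or shSix4 replicate 1 with MyoD (0.0581; range over the alternatives 0.0216 to 0.147).

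Other lists in shLuc cells held members that moved without a list-wide call under the estimated correlation. Of 30 fusion and adhesion genes 6 rose (adjusted over the list alone 8 rose and 7 fell, adjusted p = 0.374), led by the cadherin Cdh15 (8.79 ± 0.44), Itga7 (5.89 ± 0.55), the fusion protein Mymk (4.77 ± 0.37) and Adam12 (3.09 ± 0.56, above background on 1 of 3 empty-vector arrays, and 0.57 and not past the threshold with normexp). Of 19 inhibitors of myogenic bHLH factors 4 rose and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 0.119). Bhlhe41 was at 1.72 ± 0.42, Hes1 at 1.34 ± 0.25 and Snai2 at -1.20 ± 0.27. Over the alternatives Bhlhe41 read as low as 0.35 and kept its call in 12 of 23. Cdkn1c, given next as a bound, read as low as 1.30 (log2) over the alternatives. Of 17 CDK inhibitor and retinoblastoma genes 5 rose (adjusted over the list alone 6 rose and 1 fell, adjusted p = 0.119), with Cdkn1c at least 17.8-fold higher, Rb1 at 2.18 ± 0.28, Gadd45g at 1.54 ± 0.23 and Cdkn1a at 1.34 ± 0.20. Of 14 insulin-like growth factor genes 3 rose (3 adjusted over the list alone, adjusted p = 0.383): Igf2 by 8.89 ± 0.82, Igfbp5 by 5.20 ± 0.27 and Igfbp3 by 3.80 ± 0.39. Of 30 interferon response genes 1 rose and 2 fell (1 and 8 adjusted over the list alone, median -0.67, preset adjusted p = 0.000393, adjusted p = 0.496 with an estimated correlation). Trim25 rose by at least 3.01-fold, with Ifit3 at -1.28 ± 0.23 and Oas1a at -0.90 ± 0.21.

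None of 43 cell cycle genes (Cdc6 +0.85 ± 0.68), 41 fibroblast matrix genes (Fap +1.54 ± 0.52), 13 smooth muscle markers (Actg2 +1.04 ± 0.51), 16 H3K27 methylation genes (Ezh1 -0.55 ± 0.20), 23 unfolded protein response genes (Trib3 -1.09 ± 0.46) or 6 Six-Eya-Dach family genes passed with MyoD in shLuc cells by limma, over all genes or adjusted over the list alone (adjusted p 0.853 to 0.991 with an estimated correlation). At an unadjusted p under 0.05, 2374 genes of all kinds were below it, and with the slide as a block these lists held 0, 12, 3, 1, 6 and 2 calls in that order. Markers of other lineages split. Of 20 adipocyte markers 2 rose (the fatty acid transporter Cd36 by at least 3.48-fold and lipoprotein lipase Lpl by 2.21 ± 0.40) and 2 fell (Plin4 and Angptl4, -1.28 ± 0.30), against 2 and 5 adjusted over the list alone. Of 14 osteoblast markers Dmp1 rose (2.16 ± 0.30, 1 adjusted over the list alone) and of 13 chondrocyte markers Ucma rose (7.06 ± 0.98) and Papss2 fell (-1.01 ± 0.20, 1 and 1 adjusted over the list alone). Of 6 leukocyte and endothelial markers Vwf rose (1.5 ± 0.36, 2 of 3 empty-vector arrays above background) and Coro1a fell (-0.75 ± 0.17, 1 and 2 adjusted over the list alone). Of 24 cholesterol genes Dhcr7 rose (0.67 ± 0.18, 0 adjusted over the list alone), and of 26 p53 targets Cdkn1a rose and Sesn3 fell (-1.15 ± 0.19, 1 and 3 adjusted over the list alone). None of these lists passed as a whole with an estimated correlation (adjusted p 0.622 to 1.00; for cholesterol 0.661 against a preset value of 0.0131).

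In all, MyoD changed 772 of 12300 genes in shLuc cells, 580 higher and 192 lower, of which 521 and 78 by at least 2-fold. The direction was the same on all 3 slides for 766 of them, and 3223 genes (26.2%) had groups that did not overlap, where chance gives 10%. With the slide as a block 1217 genes were higher and 1936 lower, so the higher share went from 75.1% to 38.6%. All 772 were among those genes. Without shLuc replicate 1 or 3 with MyoD the unblocked count was 490 or 499. Of 60 named genes, 47 passed without any 1 array. The median of all genes shifted by -0.14 (log2), so lower calls are relative to that shift (-0.12 with quantile normalization, -0.093 with normexp and -0.16 with plain subtraction).

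In shSix4 cells, MyoD turned on the same kinds of muscle genes. Myog was at least 4594-fold higher than with empty vector, Chrng at least 746-fold, Myl1 at least 363-fold and Chrna1 at least 326-fold. Bounds, and list medians with bounds, cannot be compared in size with those in shLuc cells. They depend on the lowest signal among probes well above background on each array, which differed. On empty-vector arrays it was -5.91, -5.59 and -6.36 (log2) in shLuc cells and -4.86, -5.63 and -5.66 in shSix4 cells. Myh3 was at least 295-fold higher, the tetraspanin Tspan33 at least 211-fold, Unc45b at least 145-fold and Myh1 at least 139-fold (for Myh1 another probe in the authors' table gave 1.07 on the log2 scale and did not pass). Mylpf rose by 8.87 ± 0.40 and Tnnc2 by 8.75 ± 0.35 (n = 3 against 3). Fewer genes went down. Car6 fell by 1.78 ± 0.40 and Dgki by 1.5 ± 0.34, each above background on 2 of 3 MyoD arrays. Wnt5b fell by 1.39 ± 0.32, Gjb5 by 1.39 ± 0.26, Oas1c by 1.08 ± 0.23, the quinone reductase Nqo1 by 1.04 ± 0.21, Faah by 1.04 ± 0.20, the proteoglycan Cspg4 by 1.01 ± 0.19, Papss2 by 0.93 ± 0.20 and Hykk by 0.87 ± 0.19.

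Of the muscle lists in shSix4 cells, 35 of 52 sarcomere genes rose (45 adjusted over the list alone), with a median of 4.80, or 3.87 with bounds. Of the coupling and junction genes 21 of 30 rose (25 adjusted over the list alone, median 3.19, or 2.42 with bounds), with Hrc at least 87.7-fold higher and Stac3 up by 6.83 ± 0.48. Of the metabolism genes 8 of 22 rose (10 adjusted over the list alone, median 0.65), with Cox8b at least 43.5-fold, Mb at least 25.4-fold and Ckm at least 22.5-fold higher and Pgam2 up by 3.90 ± 0.35. Of the myogenic factors 4 of 25 rose (9 adjusted over the list alone, median 0.41), namely Myog, Rbm24 by at least 84.0-fold, Sox8 by 4.81 ± 0.78 and Vgll2 by at least 3.43-fold. Of the Notch genes 5 of 18 rose (7 adjusted over the list alone, median 0.39), with Dll1 at 5.77 ± 0.30, Mfng at least 1.76-fold higher, Hey1 at 2.14 ± 0.32 and Hes6 at 1.81 ± 0.22. With an estimated correlation the adjusted p was 0.00177 for the sarcomere, 0.00178 for coupling and junction, 0.0381 for metabolism, 0.00401 for the myogenic factors (range over the alternatives 0.00246 to 0.271) and 0.0157 for Notch, where the block gave 0.0697 (range over the alternatives 0.00637 to 0.313). Without shSix4 replicate 1 with empty vector the Notch value was 0.0847. The metabolism call ended without 8 of the 12 arrays, at 0.0579 to 0.0790: each of the shLuc empty-vector and the shSix4 MyoD arrays and shSix4 replicates 1 and 3 with empty vector (range over the alternatives 0.0254 to 0.225).

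Elsewhere in shSix4 cells 5 of 30 fusion genes rose (5 adjusted over the list alone), with Cdh15 at 8.62 ± 0.44, Itga7 at 5.41 ± 0.55, Mymk at 2.67 ± 0.37 and Ptgir at 1.74 ± 0.36. Of 17 CDK inhibitor genes 4 rose (5 adjusted over the list alone), with Cdkn1c at least 2.38-fold higher, Rb1 at 1.64 ± 0.28, Gadd45g at 1.31 ± 0.23 and Cdkn1a at 0.90 ± 0.20. Of 14 insulin-like growth factor genes 3 rose (3 adjusted over the list alone), with Igf2 at 8.04 ± 0.82, Igfbp5 at 3.91 ± 0.27 and Igfbp3 at 2.11 ± 0.39. Single members also rose: Hes1 (1.28 ± 0.25), Lpl (2.45 ± 0.40), Dmp1 (3.0 ± 0.30), Ucma (5.87 ± 0.98), Vwf (at least 1.30-fold, but -0.10 with normexp) and the chemokine Ccl5 (2.10 ± 0.22). At the preset correlation the fusion, CDK inhibitor, insulin-like growth factor, bHLH inhibitor, interferon response, cell cycle and unfolded protein lists passed in shSix4 cells, and with an estimated correlation none of them did (adjusted p 0.0579 for the bHLH inhibitors to 0.903 for cell cycle). The fusion list had a median of -0.12 and a mean of 0.63, which differ in sign. Cdkn1c and Vwf were above background on 2 of 3 MyoD arrays, Dll1 and Ucma on 2 of 3 and Sox8 on 1 of 3 empty-vector arrays.

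In all 356 genes changed in shSix4 cells, 343 higher and 13 lower (324 and 8 by at least 2-fold), and 354 in the same direction on all 3 slides. Groups of 1793 genes did not overlap (14.6%, 10% for exchangeable arrays). The block gave 701 higher and 320 lower, including all 356. Of 50 named genes, 35 passed without any 1 array. Of the genes called in each line, 322 were higher in both (16.2 for independent lists) and 10 lower in both (0.203 for independent lists), and 0 had opposite calls. The log2 changes of the 2 comparisons, which share slides but no arrays, correlated across genes at r 0.911 (rho 0.717); genes are not independent replicates. The plot of the MyoD response in both lines shows this.

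**Figure D2:**
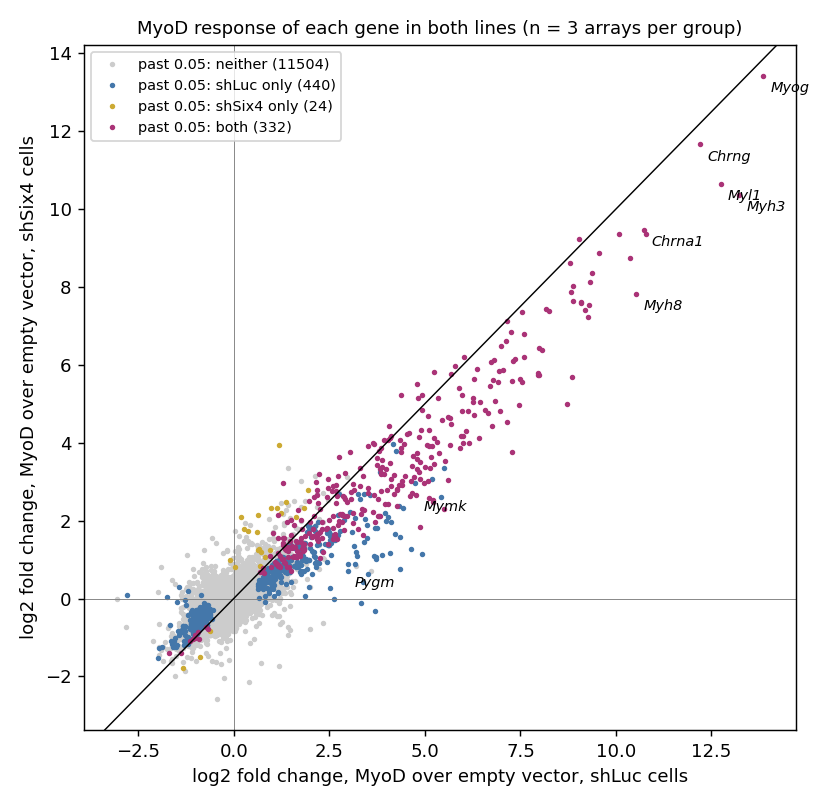
Fitted log2 change with MyoD in shLuc cells (horizontal) and in shSix4 cells (vertical), 1 point per gene for 12300 genes, coloured by which comparisons passed an adjusted p of 0.05, with a black line of equal response. Colours state which threshold was passed and not a tested difference between the lines. The points far to the right, among them muscle genes, lie mostly below the line, but choosing points by a large shLuc response favours this. Some of these genes were above background on no empty-vector array, and their sizes cannot be compared between the lines.

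With MyoD present, shSix4 cells expressed less of several muscle genes than shLuc cells. The embryonic myosin Myh3 fell by 2.40 ± 0.37 (log2, SE, n = 3 against 3), the cardiac-type myosin Myh6 by 3.09 ± 0.50, the Z-disc protein Actn2 by 2.15 ± 0.36 and the insulin-responsive glucose transporter Slc2a4 (GLUT4) by 1.80 ± 0.23, and muscle glycogen phosphorylase Pygm was at least 2.08-fold lower. Among other genes Krt23 fell by 2.61 ± 0.43, the ephrin receptor Ephb1 by 2.48 ± 0.32, Rhd by 2.18 ± 0.31 and Lrrc15 by 1.79 ± 0.26. Tmigd3 fell by 2.37 ± 0.30, and the cartilage matrilin Matn3 was at least 2.74-fold lower. In shSix4 cells with MyoD, Myh6, Krt23, Ephb1, Rhd and Lrrc15 were well above background on 2 of 3 arrays and Actn2 on 1 of 3. The chemokine Ccl5 rose by 2.44 ± 0.22, the alarmin Il33 by 2.26 ± 0.33 and the choline transporter Slc5a7 by 1.96 ± 0.33. Also higher were the peptide transporter Slc15a2 by 1.76 ± 0.23, Naip2 by 1.54 ± 0.22, Kirrel3 by 1.52 ± 0.19 and Eps8 by 1.38 ± 0.22, and Klrb1a was at least 2.12-fold higher. Slc5a7 was above background on 1 of 3 and Slc15a2 on 2 of 3 arrays of shLuc cells with MyoD. Adjusted p of these genes lay between 0.00320 (Ccl5) and 0.0471 (Actn2).

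Muscle lists moved down together in shSix4 cells with MyoD. Of 52 sarcomere genes 2 fell over all genes and 32 fell adjusted over the list alone, with a median of -1.37 (adjusted p = 0.00607 with an estimated correlation, range over the alternatives 0.00231 to 0.208) and -1.5, -1.31 and -1.21 within slides 1, 2 and 3. Of 30 coupling and junction genes 0 fell over all genes by limma (Kcnj12 -2.17 ± 0.67) and 15 adjusted over the list alone, with a median of -1.17 (adjusted p = 0.0127 with an estimated correlation, range over the alternatives 0.00543 to 0.265) and -1.34, -0.96 and -0.93 within slides. Of 22 metabolism genes 2 fell and 11 adjusted over the list alone, with a median of -0.59 (adjusted p = 0.0492 with an estimated correlation) and -0.65, -0.77 and -0.87 within slides. Normexp and the authors' table, among others, ended the sarcomere and the coupling call. With the slide as a block 25 sarcomere, 9 coupling and 9 metabolism genes fell. On the same arrays Myod1 read -1.45 ± 0.81. The metabolism call ended without any 1 array but shLuc replicate 2 with MyoD (adjusted p 0.0546 to 0.106; range over the alternatives 0.0306 to 0.20).

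Myogenic factors and smooth muscle markers were also lower in shSix4 cells with MyoD. Myogenic factors had a median of -0.35 (0 called, 3 lower adjusted over the list alone, Rbm24 -1.76 ± 0.42, adjusted p = 0.0163 with an estimated correlation) and smooth muscle markers of -0.46 (0 called, 2 lower adjusted over the list alone, Cnn1 -1.92 ± 0.47, adjusted p = 0.0475 with an estimated correlation). With the block the adjusted p was 0.0636 for the myogenic factors (range over the alternatives 0.0163 to 0.533) and 0.115 for smooth muscle (0.00951 to 0.184). Without shSix4 replicate 1 with MyoD the value for the myogenic factors was 0.106, and the smooth muscle call ended without any 1 array but shSix4 replicates 1 and 2 with empty vector (0.0538 to 0.0981).

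The other lists had no call with an estimated correlation in shSix4 cells with MyoD. Cell cycle genes had a median of -0.72 (0 of 43 called over all genes or adjusted over the list alone, preset adjusted p = 5.49e-07, adjusted p = 0.661 with an estimated correlation), but it was 0.28 on slide 1 and -1.20 and -1.21 on slides 2 and 3. CDK inhibitor genes had a median of -0.39 (0 of 17 called, 1 lower adjusted over the list alone, preset adjusted p = 0.00462, adjusted p = 0.119 with an estimated correlation), and passed with quantile normalization (adjusted p = 0.0367) and with every probe (0.0304; range over the alternatives 0.0304 to 0.805). Cholesterol genes had a median of -0.30 (0 of 24 called over all genes or adjusted over the list alone, preset adjusted p = 8.82e-05, adjusted p = 0.406 with an estimated correlation). Ccl5 was the interferon response gene that rose, with 1 higher and 1 lower of 30 adjusted over the list alone, and Matn3 the chondrocyte marker that fell (1 of 13 adjusted over the list alone). Largest members that did not pass were Mymk (-1.33 ± 0.37), Cdkn1c (-2.47 ± 0.60), Fap (-1.88 ± 0.52), Angptl4 (+1.45 ± 0.30), Hes6 (-0.90 ± 0.22) and Igf2 (-1.26 ± 0.82).

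With MyoD, 28 genes differed between the lines, 8 higher and 20 lower in shSix4 cells, all at least 2-fold and 27 in the same direction on all 3 slides. With the slide as a block it was 215 higher and 318 lower, including all 28. The count rested on single arrays. It was 1 without shLuc replicate 1, 2 or 3 with MyoD or shSix4 replicate 2 with MyoD, 6 and 14 without shSix4 replicates 1 and 3 with MyoD, 18 without shLuc replicate 1 with empty vector and 45 without shSix4 replicate 1 with empty vector. Of 19 named genes, 1 passed without any 1 array, Ccl5. Under normexp the count was 0, with Klrb1a, Slc5a7, Slc15a2 and Kirrel3 lower instead of higher. Normexp left shLuc replicate 2 with MyoD on a higher floor, with a 1st percentile of 714 against 55.2 to 58.6 on the other MyoD arrays. Whether this floor caused the turns was not tested. Groups of 1487 genes did not overlap (12.1%, 10% for exchangeable arrays, which these are not because the groups share slides).

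With empty vector, few genes passed between the lines in the fit without a block. In shSix4 cells Slc2a4 was at least 1.88-fold and the synaptic vesicle gene Svop at least 2.64-fold lower. Malic enzyme Me1 fell by 1.77 ± 0.18, the growth factor Gdf6 by 1.80 ± 0.22 (2 of 3 shSix4 arrays above background), Cd24a by 1.42 ± 0.18 and Pglyrp2 by 1.40 ± 0.19, and the adhesion protein Kirrel3 rose by 1.42 ± 0.19 (n = 3 against 3, adjusted p 0.00540 to 0.0313). These 7 genes moved alike on all 3 slides, and the block gave 18 higher and 61 lower, including all 7. Without slide 1, an alternative chosen after the data were seen, more genes differed with empty vector than with MyoD. The low count thus does not show that the lines differed less without MyoD. Slc2a4 alone passed without any 1 array. Quantile normalization called 0 higher and 4 lower, against 1 and 6, and normexp 0, with Kirrel3 at -0.11. Normexp left shLuc replicate 2 (1st percentile 1006) and shSix4 replicate 3 (197) with empty vector on higher floors than the other arrays of these groups. The count was 1 without shLuc replicate 1 or shSix4 replicate 3 with empty vector, 2 without shLuc replicate 2 with empty vector or shSix4 replicate 2 or 3 with MyoD, and 4 without shLuc replicate 3 or shSix4 replicate 2 with empty vector or shLuc replicate 1 or 2 with MyoD. Groups of 1029 genes did not overlap (8.37%, 10% for exchangeable arrays). Because the groups share slides, this does not mean fewer than chance.

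Of the lists, smooth muscle markers were lower in shSix4 cells with empty vector, with a median of -0.60 (0 of 13 called, 3 lower adjusted over the list alone, Cnn1 -2.08 ± 0.47, adjusted p = 0.0234 with an estimated correlation) and -0.33, -0.66 and -0.47 within slides. With the block the adjusted p was 0.0870 (range over the alternatives 0.00621 to 0.221). Without shLuc replicate 1 or shSix4 replicate 3 with empty vector it was 0.0744 or 0.0577. Cell cycle genes had a median of -1.03 (0 of 43 called, Ccne2 -1.62 ± 0.75, preset adjusted p = 1.82e-13, adjusted p = 0.453 with an estimated correlation), at 0.043 on slide 1 and -1.52 and -1.68 on slides 2 and 3, and with the block 20 were lower adjusted over the list alone. Interferon response genes passed at the preset correlation alone (median -0.24, preset adjusted p = 0.0268, adjusted p = 0.701 with an estimated correlation). The sarcomere list was not called (median -0.19, adjusted p = 0.856 with an estimated correlation). Lum (-1.99 ± 0.50), Cxcl12 (-1.17 ± 0.25) and Igfbp3 (+2.28 ± 0.39) did not pass. Between the 2 line comparisons, which share no arrays, 1 gene was higher in both (Kirrel3) and 4 lower in both (Slc2a4, Me1, Svop and Pglyrp2), where independent lists give 0.000650 and 0.00976, and log2 changes correlated across genes at r 0.471 (rho 0.483). With the block 15 and 41 genes were shared, against 0.315 and 1.58 for independent lists.

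**Figure D3:**
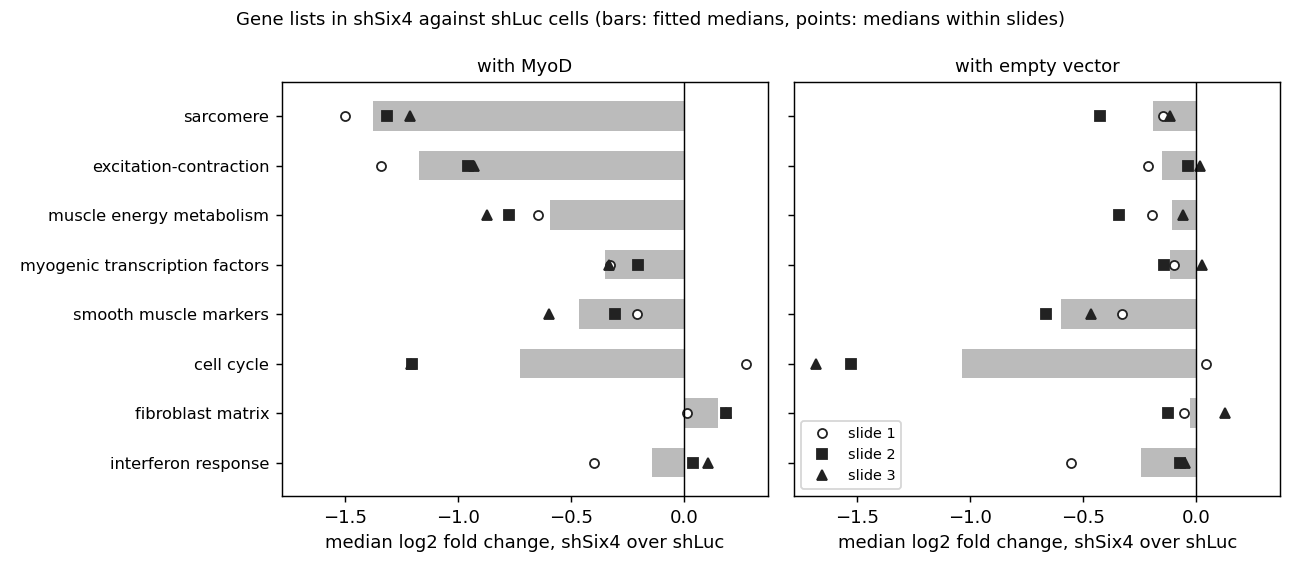
Median log2 difference of 8 gene lists between shSix4 and shLuc cells, with MyoD and with empty vector, bars for the fitted median and points for the values within slides 1, 2 and 3. The sarcomere median was -1.37 with MyoD and -0.19 with empty vector, and cell cycle points on slide 1 (0.28 and 0.043) stand apart from those on slides 2 and 3.

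The interaction tests whether the response to MyoD differed between the lines. No single gene passed by limma (0 of 12300, lowest adjusted p 0.220, 249 genes at an unadjusted p under 0.05), nor with the slide as a block (0, lowest 0.152, 768 at an unadjusted p under 0.05). With array weights 5 genes passed, chosen for naming after their values were seen. Il33 (+2.40) and Ccl5 (+2.01) responded more in shSix4 cells, at +2.76 and +1.91 in the fit without weights. Myh6, Ephb1 and Pygm responded less, and in the authors' deposited table Myh6 alone passed. These 3 genes were well above background on no empty-vector array of either line, so no size is given for them. The sarcomere and the coupling and junction lists responded less in shSix4 cells. The sarcomere median was -0.99 (10 of 52 lower adjusted over the list alone, adjusted p = 0.00567 with an estimated correlation, range over the alternatives 0.00223 to 0.262, and -1.36, -0.76 and -1.0 within slides). That of coupling and junction genes was -0.76 (0 of 30 adjusted over the list alone, adjusted p = 0.00942 with an estimated correlation, range over the alternatives 0.00526 to 0.355, and -0.99, -0.80 and -0.81 within slides). Myogenic factors had a median of -0.15 (0 of 25 adjusted over the list alone, adjusted p = 0.0163 with an estimated correlation, 0.0578 with the block, range over the alternatives 0.0110 to 0.868), and -0.019, -0.28 and -0.39 within slides, but 0.066 in the authors' table. The call for the myogenic factors ended without shLuc replicates 1 or 3 with empty vector (0.0588 and 0.0538) or shSix4 replicate 1 with MyoD (0.102). Over members measured with empty vector in both lines the medians were -0.60 (32 sarcomere genes, 28 below 0), -0.58 (14 coupling genes, 13 below 0) and -0.070 (21 myogenic factors, 12 below 0). The members with the largest fitted interactions, Myh4, Cacng1 and Sox8, were well above background on no shLuc empty-vector array, and no size is given for them. CDK inhibitor, cholesterol and leukocyte and endothelial lists passed at the preset correlation alone (adjusted p 0.184, 0.359 and 0.0677 with an estimated correlation). Metabolism genes did not pass (median -0.29, 4 of 22 lower adjusted over the list alone, adjusted p = 0.119 with an estimated correlation).

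Over the 548 genes induced by MyoD in the average of both lines, the response was lower in shSix4 cells, with a median interaction of -0.61 (1.52-fold) and 448 genes below 0. It was -0.68, -0.59 and -0.59 within slides 1, 2 and 3 (adjusted p = 0.00875 by camera with an estimated correlation, range over the alternatives 0.00345 to 0.114). By fry it did not pass (adjusted p = 0.0749, and 0.0137 with the slide as a block). The camera call ended without shSix4 replicate 1 with empty vector (median -0.53, adjusted p = 0.0608). An absolute median as large came from 18 of 100 drawn splits of the 12 arrays, the real one included. Of these, 13 kept the MyoD arrays parted by line and so kept the difference between the lines with MyoD, and the 5 others reached 0.735. This share therefore cannot decide about chance. With the line exchanged within slides, splits that mixed the MyoD arrays reached at most 0.395. Adjusted over the list alone, 27 of the 548 genes had a lower and 2 a higher response, and 132 and 11 with the block. Their median response was 2.54 in shLuc and 1.97 in shSix4 cells. Among the 353 of these genes well above background on at least 1 empty-vector array of each line the median interaction was -0.47. Set against shLuc cells with MyoD, the induced genes had a median of -0.76 (475 below 0; 188 lower and 9 higher adjusted over the list alone; adjusted p = 0.00875 by camera with an estimated correlation, range over the alternatives 0.00345 to 0.114, and 0.0145 by fry), and with empty vector of -0.053 (adjusted p = 0.909 with an estimated correlation). The 66 repressed genes had a median interaction of 0.26, which did not pass (adjusted p = 0.687 with an estimated correlation; -0.15, 0.48 and 0.28 within slides).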

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

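Among the tests in this part, those of the Myod1 level, of slide or scan day, of both explanations for the cell cycle genes and of another difference between the stable lines were chosen after the result was seen, as was the look at which splits part the MyoD arrays by line. Because the response to MyoD differed between the lines by camera with an estimated correlation, these results were looked at again: the median interaction was -0.99 for sarcomere genes, -0.15 for myogenic transcription factors and cofactors, -0.76 for coupling and junction genes and -0.61 for the 548 MyoD-induced genes. Over members measured with empty vector in both lines these medians were -0.60, -0.070 (12 of 21 below 0), -0.58 and -0.47 in that order. The call for the myogenic factors ended with the slide as a block, and their median was above 0 in the authors' table. A signal outside the tested genes was also seen. Of 6181 tested probes without a gene name, 185 rose and 25 fell with MyoD in shLuc cells (111 and 0 in shSix4 cells; with the slide as a block 424 and 520, and 220 and 38), and these transcripts were not identified here.

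The MyoD-induced genes were lower in shSix4 than in shLuc cells with MyoD, by a median of -0.76, and the tables argue against slide or scan day as the cause, since the median was between -0.84 and -0.71 within each slide. They also argue against 1 lower share of converted cells as the only source of the differences. This was examined among 66 induced genes measured on all 6 MyoD arrays and on no empty-vector array. Their differences ran from -1.94 to -0.32 (10th to 90th percentile, median -1.22, 63 below 0). The gene-by-gene pattern recurred between slides with the level regressed out (r 0.435, 0.476 and 0.759). In 1000 shuffles, run for slides 1 and 2 alone, r was at most 0.403. A lower share together with differences between the lines in single genes could give the same pattern and is not excluded. A lower level of the introduced MyoD cannot be told apart from an effect of Six4 loss. Myod1 was itself -1.45 in shSix4 cells with MyoD, not past the threshold, and the design does not vary its level apart from the line. Whether the probe reads the viral transcript is not given, so this value may not be the level of the introduced MyoD. Within slides 1, 2 and 3 Myod1 differed by -2.24, -0.64 and -1.46 and the induced genes by -0.73, -0.84 and -0.71, so the slides did not rank alike, as a graded response to Myod1 would need, and 3 slides with medians this close do not exclude it. An effect of lower Six4 on the muscle programme stays open as a hypothesis and was not tested apart from the Myod1 level.

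Cell cycle genes were lower in shSix4 cells on slides 2 and 3 and not on slide 1. The tables argue against the same knockdown effect on every slide, since the list median with MyoD was 0.28 on slide 1 but -1.20 and -1.21 on slides 2 and 3, and down to -1.68 with empty vector. What set slide 1 apart cannot be told from these medians, since the pattern was itself seen as a difference between slides: with empty vector the slide 1 median was 0.043, and 16 of 43 members were lower there against 42 and 42 on slides 2 and 3 (6, 41 and 43 with MyoD). By array, the list's median level in shSix4 cells was 2.48 and 2.91 on slide 1 and 0.53 to 1.37 on the others, while shLuc arrays lay between 2.19 and 2.77. The shSix4 arrays thus differed and not the slide as a whole. The labels do not say whether these were separate cultures. Whether the cells behind the shSix4 arrays of slides 2 and 3 were denser or had left the cycle earlier was not tested, and the scan day goes with slide 1.

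The difference between shSix4 and shLuc cells was partly shared between the vectors, with 56 genes called in both comparisons with the slide as a block. Samples of a line that shared a slide may account for part of it: across genes, differences on the same slide correlated at r 0.282 to 0.502, and those on different slides at 0.0955 to 0.456. These ranges overlap only through the pairs between slides 2 and 3 (0.395 and 0.456). Pairs of slide 1 with another slide gave 0.0955 to 0.170, against 0.338 within slide 1. The shared difference was thus weak between slide 1 and the other slides. A part shared by slide cannot be told apart from a part shared by line. Each hairpin was in 1 stable line, so the 56 genes cannot be told apart from a difference between the lines other than the Six4 level. An effect of Six4 loss present with either vector stays open and was not tested separately.

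For each comparison of 3 against 3 arrays there are 10 splits of the 6 arrays, too few for a share under 0.05. In each comparison 1 split, the real one, gave the largest count: 772 genes for MyoD in shLuc cells (highest other 0), 356 for MyoD in shSix4 cells (highest other 1), 28 for the lines with MyoD (highest other 0) and 7 with empty vector (highest other 0). For the interaction, 100 splits were drawn. As no gene was called (limma, 249 at an unadjusted p under 0.05), all 100 gave at least as many, and 4 called genes, up to 2252. That highest split put shLuc replicates 1 and 2 and shSix4 replicate 1 with empty vector under 1 label. Under the same label it put shLuc replicates 2 and 3 and shSix4 replicate 3 with MyoD. Both slide 1 empty-vector arrays thus stood apart from both slide 1 MyoD arrays, so its interaction by construction adds differences of slide 1. This layout was looked at after the counts were seen. The other drawn splits with the most genes at an unadjusted p under 0.05 (4144, 3616, 2913, 2910 and 2615) share it and called 0 genes. The other 3 splits that called genes (91, 15 and 9 genes) parted the MyoD arrays by line. With the line exchanged within slides 3 of 32 splits called genes (1096, 2 and 1 with the block). The split with 1096 exchanged the line on every empty-vector array, which by construction adds the differences between the lines with both vectors.

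For the median interaction of the induced genes (-0.61), 18 of the 100 drawn splits gave an absolute median as large, up to 0.872, so these splits do not exclude chance. Of those 18, 13 kept the MyoD arrays parted by line, out of 14 such splits, and the 5 others reached 0.735. With the line exchanged within slides, 8 of 32 splits gave an absolute median as large, up to 0.861, which does not exclude chance either. All 8 kept the MyoD arrays parted by line, and the rest reached at most 0.395. Such splits keep the difference between the lines with MyoD that the count was to judge. As the induced genes had a median difference of only -0.053 with empty vector, exchanges there leave the value large. Neither share can therefore decide about chance. The 7 that exchanged the line among empty-vector arrays alone gave -0.641 to -0.861, each larger in size than the real value. The value within slides was -0.68, -0.59 and -0.59.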

How the results depend on the processing

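The alternatives without slide 1, with plain background subtraction and with the shared-gene count under the block or without slide 1 were chosen after the data were seen, and the cause of a change was not tested unless given. Counts below are in the order MyoD in shLuc, MyoD in shSix4, shSix4 against shLuc with MyoD and with empty vector.

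With normexp the counts were 86, 49, 0 and 0. The 176 induced genes had a median interaction of -0.40 and a median difference of -0.72 with MyoD (adjusted p = 0.114 for each, range over the alternatives 0.00345 to 0.114 for each). Myod1 read 2.07 in shLuc cells (adjusted p = 0.930, range 0.00257 to 0.930). Vwf in shSix4 cells (-0.10), Klrb1a (-0.35), Slc5a7 (-0.24), Slc15a2 (-0.073) and Kirrel3 (-0.33 with MyoD and -0.11 with empty vector) turned direction. Of the 136 named gene values 86 became over 1.5 times smaller or turned with normexp and 67 with plain subtraction, and 93 and 47 lost their call. Normexp left the arrays on different floors, with a 1st percentile of 1006 for shLuc replicate 2 with empty vector, 714 for shLuc replicate 2 with MyoD and 197 for shSix4 replicate 3 with empty vector, against 55.0 to 58.6 on the others.

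Quantile normalization gave 4 genes with empty vector and 2 shared between the vectors. The authors' table, which holds fewer genes, gave 157, 51 and, with empty vector, 3, and 1 gene in the interaction (Myh6, adjusted p = 0.00779, lowest adjusted p of any gene over the alternatives 0.00779 to 1.00), with a median interaction of 0.066 for the myogenic factors. With no filter the line comparisons gave 2 and 2, and Myod1 rose by 4.03 (adjusted p = 0.0542) among more genes tested. With probes well above background on all arrays the counts were 457, 154, 6 and 4, with 3 shared, and the Notch median in shLuc cells was -0.0072. Every probe gave 4 with empty vector. Only the groups compared, with fewer residual degrees of freedom, gave 227 for MyoD in shSix4 cells and 0 and 0 for the lines. The replicate number or the slide as a block gave 3153, 1021, 533 and 79 with 56 shared, and Six4 at -1.17 passed (adjusted p = 0.0424, range 0.0424 to 0.961).

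Trended and robust moderation gave 2 and 3 for the lines. Array weights gave 1297, 668, 430 and 165 and 5 genes in the interaction, chosen for naming after their values were seen: Ccl5, Ephb1, Il33, Myh6 and Pygm (adjusted p = 0.0435). Plain subtraction gave 46 and 0 for the lines. Without slide 1 the lines differed in 271 and 280 genes with 136 shared, and the induced genes had a median interaction of -0.57 and a median difference of -0.84 with MyoD, past the threshold in neither (adjusted p = 0.0693 for each, with fewer arrays).

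Leaving out each array gave 490 to 876, 266 to 367, 1 to 45 and 1 to 9 genes and 0 in the interaction by limma. Medians for the induced genes were -0.79 to -0.44 (interaction) and -0.97 to -0.56 (with MyoD), and for the repressed genes 0.044 to 0.39. Six4 lay between -1.65 and -0.91 with MyoD and between -1.18 and -0.53 with empty vector. Myod1 rose by 2.93 to 5.13 in shLuc cells and read 0.92 to 3.28 in shSix4 cells. A lone array in a group is assumed to vary like the other groups. Without shSix4 replicate 3 with empty vector the bHLH inhibitors in shSix4 cells (range over the alternatives 0.0327 to 0.772) and the leukocyte and endothelial markers in the interaction gained a call (adjusted p = 0.0482 for each).

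Over all other alternatives, named genes kept direction and side of the threshold in 1272 cases, lost the call in 306 and turned in 6; lists did so in 1153, 103 and 2. In a further 126 cases a list that passed under neither setting changed sign. A list gained a call in 4 cases: CDK inhibitors with quantile normalization (adjusted p = 0.0367 with MyoD in shLuc cells and between the lines with MyoD) and with every probe (0.0304 between the lines with MyoD), and bHLH inhibitors in shSix4 cells with every probe (0.0327). The sarcomere call in shSix4 against shLuc cells with MyoD (adjusted p 0.00231 to 0.208 over the alternatives) and in the interaction (0.00223 to 0.262) was lost with normexp, the authors' table, plain subtraction and without slide 1, and the first also with only the groups compared. The coupling call was lost with the same alternatives in both (0.00543 to 0.265 and 0.00526 to 0.355), and also with only the groups compared (lines with MyoD) or no filter (interaction). For MyoD in either line the sarcomere and coupling lists had an adjusted p of 0.000840 to 0.0931, lost without slide 1, in shLuc cells with only the groups compared and, for coupling, with normexp. The myogenic factors lost their call for MyoD in shLuc cells (0.00240 to 0.367) and in shSix4 cells (0.00246 to 0.271) with the authors' table, only the groups compared, plain subtraction and without slide 1, and in shSix4 cells also with probes well above background on all arrays. Signal over background limits the changes given as bounds, and few arrays per group limit the smallest change that passes.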

Other observations

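No hypothesis was tested in this part, and its values were chosen after they were seen. The genes that shared a difference between the lines with either vector were not muscle genes alone. Of the 5 genes called in both without the block, Slc2a4 takes up glucose in muscle and fat, Me1 makes NADPH for lipid synthesis, Svop sits on synaptic vesicles, Pglyrp2 cleaves peptidoglycan and Kirrel3 joins cells. With MyoD they differed by -1.80, -1.64, -1.50, -1.28 and +1.52, and Me1 by -1.77 with empty vector.

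Repressed genes chosen by their call in shLuc cells show why the sets were chosen on the average of both lines. The 78 genes lower by at least 2-fold in shLuc cells had a median interaction of 0.48 (77 above 0), against 0.26 for the 66 chosen on the average, a choice that favours large changes in shLuc cells. For the induced genes the values were -0.70 over 521 genes and -0.61 over 548.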
